A study of Mus musculus with 9 samples.

How the data were processed

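Gene expression was measured on 9 arrays of total RNA from N1E-115, a mouse neuroblastoma line. Per the labels, 3 arrays came from cells overexpressing mouse Tcof1, 3 from wildtype cells and 3 from cells with Tcof1 knocked down, each group lettered A, B and C. How Tcof1 was raised or lowered, and whether the letters stand for separate cultures, is not given in the sources used here. The p-values therefore measure only the spread between these arrays, which may be technical.

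The authors deposited linear intensity values of a 1-colour array, 1 per probe set and array, with names of the Affymetrix kind. The software, the background correction and the scaling are not given in the sources used here. The mean without the lowest and highest 2% of values was 499.93 on each of the 9 arrays, so the deposited intensities had been scaled to a common level. The table held no detection calls, so probe sets near background could not be set aside by a call. The number of arrays limits the precision.

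Of 22690 probe sets, 64 were control probe sets and were left out of the tests. Among the other 22626, 20380 had exactly 1 gene symbol in the platform annotation, 691 had several and 1555 had none. Only probe sets with exactly 1 symbol were named. Of these, 20351 matched a gene of the RefSeq table of assembly GRCm38.p6 by gene identifier, and 0 symbols needed updating. That table served only for names, gene order and shared chromosomes, and no coordinates are given because no build is named for the array.

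The array medians lay between 164.1 and 185.95, a ratio of 1.13, which was under the limit of 1.2 fixed for rescaling, so the values were used as deposited. They were converted to log2(intensity + 16), which understates the change of dim probe sets. limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend) was fitted to all 9 arrays at once with a mean per group. The contrasts were overexpressed over wildtype, knockdown over wildtype, and overexpressed over knockdown. Benjamini-Hochberg adjustment ran over the 22626 probe sets within each contrast, and an adjusted p under 0.05 was a call. Fold changes are log2 values ± SE from this fit, and intensities are means ± SD over 3 arrays.

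Before the data were examined, 20 gene lists were fixed, with 975 entries of which 861 were measured. They covered treacle partners and Treacher Collins genes, RNA polymerase I and ribosome biogenesis, cytosolic ribosomal proteins, DNA replication and S phase, mitosis, p53 targets, apoptosis regulators, neural crest and craniofacial regulators, neuronal and catecholaminergic markers, neurite growth and cytoskeleton, and the type I interferon response. They also covered endoplasmic reticulum and amino acid stress, the heat shock response, sterol and fatty acid synthesis, oxidative phosphorylation, glycolysis and hypoxia targets, immediate early genes, fibroblast and matrix markers, Schwann cell and glia markers, and blood and immune cell markers. Each gene was represented by its brightest probe set. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 20 lists per comparison. Camera with an estimated correlation, and fry, which asks whether a list's genes move one way without setting them against other genes, were alternatives.

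Genes to be named were also fixed by rule before the data were examined. Tcof1 was named throughout. Per comparison, up to 12 higher and 12 lower genes were named by absolute fold among calls with 1 symbol, non-overlapping groups and a brighter group above the median of all probe sets. Up to 4 members per list with the smallest p were added. Where fewer than 5 probe sets were called, the 10 with the smallest p were named. Of the probe sets called against wildtype in both comparisons, up to 8 in opposite directions and up to 8 in the same direction were named.

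The shared letters were not used as pairs. Because both comparisons with wildtype use the same 3 wildtype arrays, the values that unchanged groups would give were simulated 100 times. The wildtype arrays could not be split, as 3 arrays do not leave at least 2 in each part.

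The fit was tested on simulated arrays with the real probe means and residual SDs. In overexpressed over wildtype, 200 of 22626 probe sets were changed, all drawn from those brighter than the median. The fit recovered 42% of 1.5-fold, 76% of 2-fold, 92% of 3-fold and 98% of 4-fold changes, with 11 false calls. The changes were added on the log2 scale, and recovery for dimmer probe sets was not tested. The list test called the 1 shifted list and 0 of the others. These simulated probe sets varied independently, unlike those of real arrays.

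Alternatives were pseudocounts of 1 and 64, only probe sets above the 40th percentile of brightness, quantile normalization, a common array median, no mean-variance trend, array quality weights, the letter as a block, a further 1.5-fold limit, no probe sets of types s, x, f, g, i and r, the mean of all probe sets of a gene, only the 6 arrays compared, and each array left out in turn. The types left out can match several transcripts, and sets ending in _a_at were kept. Chromosome analyses used the brightest probe set per gene with mean log2 above 8, in NumPy 2.4.6 and SciPy 1.17.1 under Python 3.11.15, with 10000 permutations of genes. Figures were drawn with matplotlib 3.10.9.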

Results

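RNA of the neuroblastoma line N1E-115 was compared between cells overexpressing Tcof1, wildtype cells and cells with Tcof1 knocked down, with 3 arrays per group. Tcof1 encodes treacle, a nucleolar protein that acts in the transcription of ribosomal RNA genes and is mutated in Treacher Collins syndrome. The design asks what raised and lowered Tcof1 do to the other transcripts of these cells. Array medians lay between 164.1 and 185.95 intensity units. Correlations of log2 values were 0.972 to 0.978 within groups and 0.956 to 0.978 between groups.

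Tcof1 itself was higher in the overexpressing cells, and a reduction in the knockdown cells was not detected. Its 3 probe sets, told apart by the endings of their names, differed in size of change. The set ending in _a_at read 293.8 ± 80.9 (SD, n = 3) in overexpressing, 149.7 ± 6.60 in wildtype and 126.6 ± 12.6 in knockdown arrays. The set ending in _s_at, a type that can match several transcripts, read 263.4 ± 29.6, 166.5 ± 36.4 and 121.2 ± 14.0 in the same order. The brightest, ending in _at alone, read 278.5 ± 12.7, 210.9 ± 37.3 and 217.9 ± 12.1. Against wildtype, the overexpressed log2 fold changes were 0.87 ± 0.21 (adjusted p = 0.0241), 0.63 ± 0.20 (adjusted p = 0.0786) and 0.39 ± 0.17 (adjusted p = 0.187), so 1 of the 3 passed. Knockdown over wildtype gave -0.22 ± 0.21 (adjusted p = 0.744), -0.40 ± 0.20 (adjusted p = 0.51) and 0.06 ± 0.17 (adjusted p = 0.934), and none of the 3 passed. Between overexpressing and knockdown cells, the first and second probe sets differed by 1.09 ± 0.21 (adjusted p = 0.0116) and 1.03 ± 0.20 (adjusted p = 0.0137), and the brightest by 0.33 ± 0.17 (adjusted p = 0.267). The knockdown label is therefore not checked against wildtype by these probe sets.

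**Figure D1:**
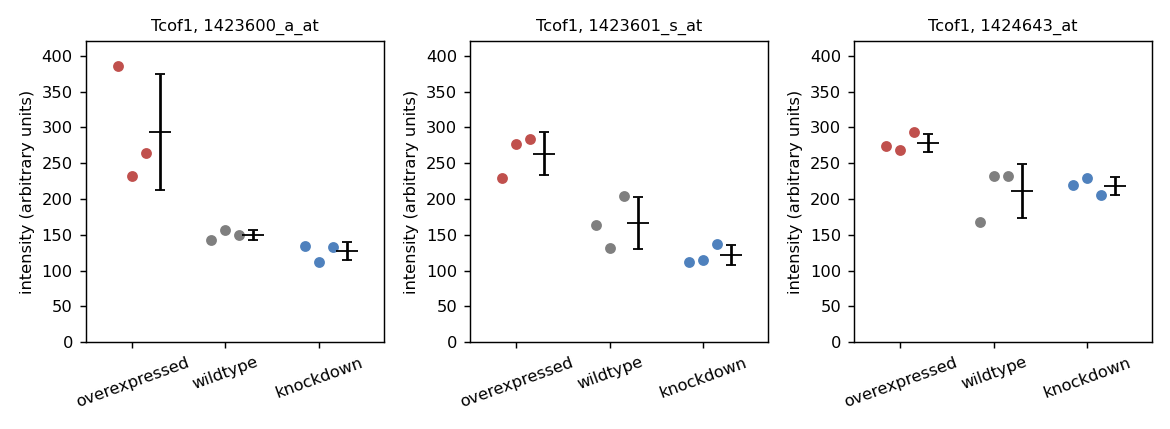
Intensity of the 3 Tcof1 probe sets on each array (points), with the mean and SD of the 3 arrays per group (bars), on axes from 0. On the set ending in _a_at the overexpressing arrays averaged 293.8 and the wildtype arrays 149.7.

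In cells overexpressing Tcof1, 40 of 49 DNA replication genes and 26 of 75 genes of ribosome production rose. The mitosis list was also called higher, and the interferon, glycolysis and hypoxia, neuronal, sterol and fibroblast lists lower. These 6 calls were lost with an estimated correlation (adjusted p = 0.193 to 0.554). By fry the mitosis, interferon, glycolysis and hypoxia, and neuronal lists passed (adjusted p = 0.00238 to 0.00813). The sterol and fibroblast lists did not (adjusted p = 0.0693 and 0.0643 by fry). The ribonucleotide reductase subunit Rrm2 rose by 2.50 ± 0.42 (adjusted p = 0.0049), and follistatin, encoded by Fst, by 2.30 ± 0.15 (adjusted p = 4.61e-05). Dlk1, a Notch-related membrane protein, was the most reduced of the genes named by rule, at -3.51 ± 0.16 (adjusted p = 6.04e-06). Foxm1, a transcription factor of mitotic genes, was higher by 2.53 ± 0.29 (adjusted p = 0.000786) on 1 of 4 probe sets, which read 17.5 in wildtype arrays. The others, at 0.55 ± 0.22, 0.41 ± 0.22 and 0.13 ± 0.36, did not pass. Of 22626 probe sets, 2169 passed, 1022 higher and 1147 lower, for 1640 genes. The share that was higher was 47.1%, but 52.0% with a common array median and 50.7% without wildtype array C.

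Among the DNA replication and S phase genes, 40 of 49 rose and 0 fell, with a list median of 0.99. Adjusted over the list alone, 46 rose. Mcm5 and Mcm10, parts and partners of the replicative helicase, rose by 2.18 ± 0.22 and 1.47 ± 0.14, Pcna, the sliding clamp, by 1.37 ± 0.15, and Rpa2, which binds single-stranded DNA, by 1.46 ± 0.17. The list passed camera (adjusted p = 2.08e-33). Of 47 mitosis genes, 29 rose and 1 fell, or 39 and 1 adjusted over the list alone, with a median of 0.86. Aurka and Cdk1, mitotic kinases, rose by 1.08 ± 0.14 and 1.11 ± 0.15, Tpx2 by 0.94 ± 0.13 and Ube2c by 0.92 ± 0.13. The mitosis list passed camera (adjusted p = 9.41e-21), with adjusted p = 0.195 with an estimated correlation.

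Of 75 genes of RNA polymerase I and ribosome biogenesis, 26 rose and 0 fell, with a median of 0.33 (camera adjusted p = 1.23e-13). Adjusted over the list alone, 37 rose and 3 fell. Nop56, a core protein of box C/D small nucleolar particles, rose by 1.28 ± 0.11, Exosc2 of the RNA exosome by 0.92 ± 0.10, Tsr1 by 0.88 ± 0.11 and Mphosph10 by 0.58 ± 0.09. Treacle partners and Treacher Collins genes shared 9 measured genes with that list, and 6 of 17 rose, or 10 adjusted over the list alone, with a median of 0.34 (camera adjusted p = 9.8e-06). They included Nolc1, a nucleolar relative of treacle, at 0.63 ± 0.12, Plk1 at 0.90 ± 0.18 and Topbp1 at 1.59 ± 0.32. Of 43 genes of cytosolic ribosomal proteins, 0 rose and 1 fell, Rps25 at -0.29 ± 0.08 (adjusted p = 0.0401), or 0 and 0 adjusted over the list alone. Their median of -0.04 turned to 0.02 with quantile normalization and to 0.01 without wildtype array A, and the list did not pass (camera adjusted p = 0.653).

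Of 43 interferon response genes, 15 fell and 0 rose, or 17 and 1 adjusted over the list alone, with a median of -0.32. The antiviral genes Rsad2 and Ifit1 were lower, at -2.52 ± 0.23 and -1.90 ± 0.17, Ifitm3 at -1.02 ± 0.11, and Tapbp, which helps to load MHC class I, at -1.09 ± 0.12. The list passed camera at adjusted p = 3.56e-06, but had adjusted p = 0.193 with an estimated correlation. Among 37 glycolysis and hypoxia targets, 12 fell and 2 rose, or 17 and 3 adjusted over the list alone, with a median of -0.32. The aldolase gene Aldoc changed by -2.48 ± 0.15, P4ha2 by -0.83 ± 0.08, Egln3 by -0.98 ± 0.10 and the glucose transporter gene Slc2a3 by -0.68 ± 0.09. A second Aldoc probe set had the opposite sign. By camera, adjusted p was 4.8e-05, and adjusted p = 0.195 with an estimated correlation.

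Of 59 neuronal and catecholaminergic markers, 12 fell and 2 rose, or 16 and 3 adjusted over the list alone, with a median of -0.13. Neuronal enolase, Eno2, changed by -1.84 ± 0.15, acetylcholinesterase, Ache, by -1.40 ± 0.14, Nrcam by -1.03 ± 0.12 and Chga by -0.75 ± 0.12. In camera the list had adjusted p = 0.00502, and adjusted p = 0.273 with an estimated correlation. Its median was -0.20 without wildtype array A. Of 33 sterol and fatty acid synthesis genes, 10 fell and 0 rose, or 12 and 3 adjusted over the list alone, with a median of -0.26, among them Acss2 at -1.23 ± 0.11 and Tm7sf2 at -1.01 ± 0.11. Camera gave adjusted p = 0.0041, and adjusted p = 0.554 with an estimated correlation. Without wildtype array C the sterol list did not pass (adjusted p = 0.169), and fry gave adjusted p = 0.0693. The sterol median was -0.14 without wildtype array B and -0.37 without wildtype array A, which at -0.28 lay among the overexpressing arrays (-0.30 to -0.14). Of 40 fibroblast and matrix markers, 9 fell and 1 rose, and as many adjusted over the list alone, with Pdgfrb at -2.01 ± 0.33 and Igfbp5 at 1.41 ± 0.21. That list passed narrowly (median -0.13, adjusted p = 0.0443), with adjusted p = 0.49 with an estimated correlation and 0.0526 to 0.118 under other alternatives that ended the call, among them leaving out overexpressed array A or B, or wildtype array B or C. Its median ran from -0.19 without overexpressed array B to -0.07 without wildtype array B. Pdgfrb read 22.5 in overexpressing arrays, near the 16 added before the log, and no other probe set of Pdgfrb or Igfbp5 passed.

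The other 10 lists did not pass camera in overexpressed over wildtype, with adjusted p from 0.172 to 0.998. Members of several moved in both directions. Of 61 neural crest and craniofacial regulators, 8 rose and 2 fell, or 10 and 4 adjusted over the list alone, and the inhibitors of bHLH factors Id1 and Id3 rose by 1.05 ± 0.09 and 1.62 ± 0.17, and Id2 by 2.18 ± 0.35 on its most changed probe set. The list's median was -0.05, which turned to 0.08 without overexpressed array C, and its mean 0.11. Endoplasmic reticulum and amino acid stress had 6 that rose and 3 that fell of 48 (7 and 4 adjusted over the list alone), with Manf at 1.14 ± 0.17. Its median was -0.03, or -0.004 without overexpressed array C, with a mean of 0.04. Neurite growth and cytoskeleton had 4 and 6 of 55 (4 and 6), with Rhob at -1.37 ± 0.16. Immediate early genes had 2 and 2 of 39 (2 and 2), with Egr1 at -1.68 ± 0.22, a mean of -0.01 and a median of 0.04 that ran from -0.02 without overexpressed array B to 0.09 without wildtype array B. Apoptosis regulators had 1 and 3 of 37 (3 and 4), with Pdcd4 at -1.44 ± 0.14. The heat shock response had 1 and 2 of 33 (2 and 2), with a median of -0.01 against an upward camera direction, and oxidative phosphorylation 2 and 1 of 65 (1 and 1), with a median of -0.01 and a mean of 0.01. Without wildtype array B these 2 medians turned to 0.04 and 0.02. Of 30 p53 targets 1 rose (1 and 0 adjusted over the list alone), Aen at 0.57 ± 0.12 with another probe set of opposite sign, and a median of -0.10 against an upward camera direction. That median ran from -0.16 without overexpressed array B to -0.06 without wildtype array B. Schwann cell and glia markers had 1 and 2 of 23 (1 and 2), with Clu at -1.49 ± 0.21, and blood and immune cell markers 1 and 1 of 27 (0 and 1), with Cd74 at -1.28 ± 0.12.

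Other genes with large changes were the replication licensing factor Cdc6 at 2.24 ± 0.34, Trip13 at 2.12 ± 0.29, Dlx1 at 2.12 ± 0.23, Pclaf at 2.0 ± 0.25, Dtl at 1.95 ± 0.24, Rrp9 at 1.91 ± 0.33, Gins1 at 1.88 ± 0.25 and Brca1 at 1.86 ± 0.28. Of 3 other Brca1 probe sets, 2 passed in the same direction and 1 had the opposite sign without passing. Pclaf and Dtl each had 1 other probe set, which did not pass. Dlx1 read 10.5 in wildtype arrays. On the lower side were Clu by its most changed probe set at -2.84 ± 0.28, Adam23 at -2.62 ± 0.22, Ddx17 at -2.52 ± 0.39, Ndrg1 at -2.51 ± 0.27, Adgrg1 at -2.49 ± 0.34, Masp1 at -2.44 ± 0.40, Pcp4 at -2.27 ± 0.15, Bmp7 at -2.26 ± 0.22 and Prom1 at -2.25 ± 0.13. In overexpressing arrays Ddx17 read 18.3, Ndrg1 24.4 and Masp1 20.9, near the 16 added before the log. The groups did not overlap for 27.8% of probe sets, where chance gives 10%. Without the mean-variance trend 1339 probe sets passed. The count was 1197 without overexpressed array A, 1288 without overexpressed B, 1347 without wildtype A and 1090 without wildtype B, and 2026 with chromosome medians removed, an adjustment chosen after the data were seen.

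**Figure D2:**
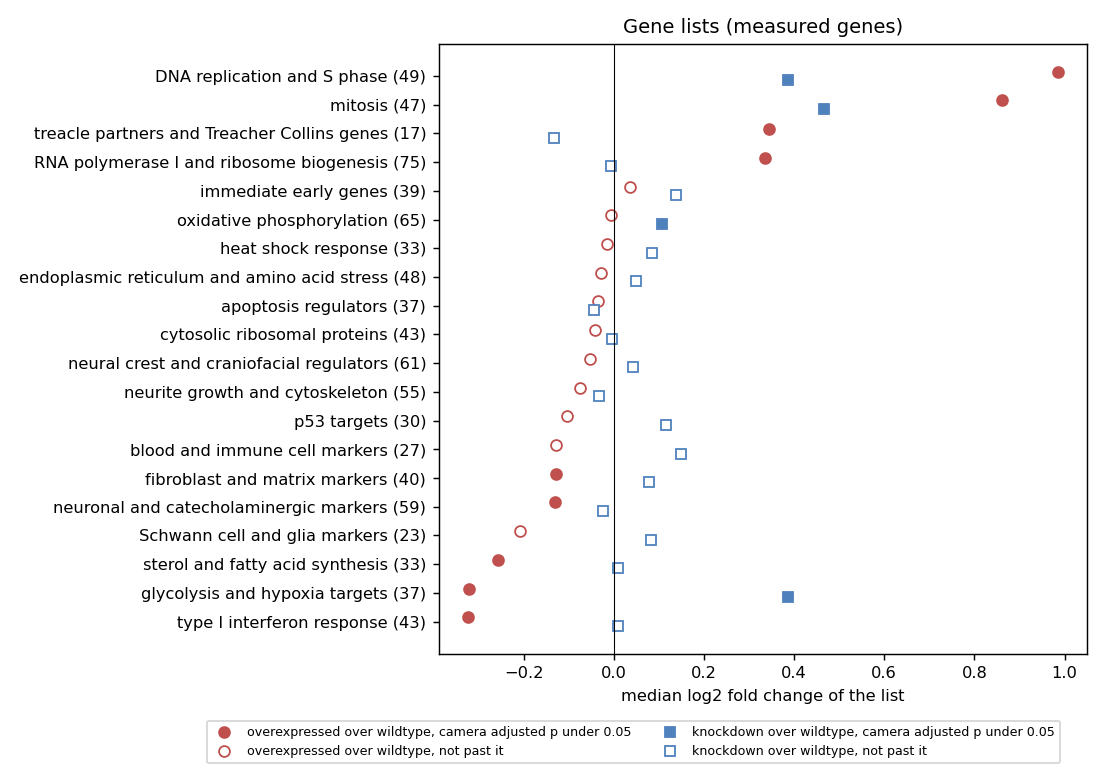
Median log2 fold change (horizontal axis) of each of the 20 gene lists, with the number of measured genes in parentheses, for overexpressed over wildtype (circles) and knockdown over wildtype (squares). Filled symbols passed camera at the preset correlation, 9 lists in the first comparison and 4 in the second.

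In the knockdown cells, 3 probe sets passed against wildtype in limma, 1 higher and 2 lower, with 2462 at an unadjusted p under 0.05. The replication, mitosis, and glycolysis and hypoxia lists had medians of 0.39, 0.47 and 0.39 and passed camera, with 0 members past over all probe sets. These calls were lost with an estimated correlation (adjusted p = 0.216, 0.37 and 0.0905), and by fry had adjusted p = 0.0415, 0.136 and 0.00452. Srrm1, which encodes a splicing cofactor, fell by 2.35 ± 0.25 on the log2 scale on 1 of its 4 probe sets (adjusted p = 0.0324). Arih2, a ubiquitin ligase gene, fell by 1.0 ± 0.12 on 1 of 4, of a type that can match several transcripts (adjusted p = 0.0336). For each of these genes 1 other probe set had the opposite sign. A bright probe set with no single gene symbol rose by 0.88 ± 0.10 (adjusted p = 0.0336).

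The next smallest p-values did not pass. They belonged to Adm, the gene of the hypoxia-induced peptide adrenomedullin, at 2.78 ± 0.36 (adjusted p = 0.0558), Tex43 at 1.77 ± 0.24, Trim35 at -0.73 ± 0.10, Ppp2r5c at -1.96 ± 0.27, Fzd6 at -1.03 ± 0.14, Wdr6 at -0.53 ± 0.07 (each adjusted p = 0.057) and Sema6a at -1.71 ± 0.25 (adjusted p = 0.0673). Of 37 glycolysis and hypoxia targets, 0 passed over all probe sets, and 21 rose and 1 fell adjusted over the list alone, with a median of 0.39. Hexokinase gene Hk2 was at 1.02 ± 0.15, the lactate transporter gene Slc16a3 at 0.95 ± 0.14 and Ero1a at 0.55 ± 0.09 (each adjusted p = 0.0701 over all probe sets). The list passed camera (adjusted p = 4.87e-15), with adjusted p = 0.0905 with an estimated correlation.

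Of 49 DNA replication and S phase genes, 0 passed over all probe sets and 19 rose adjusted over the list alone, with a median of 0.39. Mcm5 was at 1.32 ± 0.22 (adjusted p = 0.0847), and Tk1 and Pcna at 1.09 ± 0.24 and 0.69 ± 0.15 (each adjusted p = 0.148). The list passed camera at adjusted p = 2.05e-14, but had adjusted p = 0.216 with an estimated correlation. Of 47 mitosis genes, 0 passed and 4 rose adjusted over the list alone, with a median of 0.47 and Cdk1 at 0.82 ± 0.15 (adjusted p = 0.0952). By camera, adjusted p was 9.37e-15, and adjusted p = 0.37 with an estimated correlation. Fry gave adjusted p = 0.136 for this list. Its median was 0.28 without wildtype array A and 0.63 without wildtype array C, and its wildtype arrays spread from -0.37 to 0.30, against 0.40 to 0.53 in knockdown arrays. Oxidative phosphorylation had a median of 0.11, with 0 of 65 past over all probe sets and 0 adjusted over the list alone. Ndufb3, of respiratory complex I, was at 0.33 ± 0.08 (adjusted p = 0.173). In camera the list had adjusted p = 0.000242, and adjusted p = 0.166 with an estimated correlation and 0.0181 by fry. Without knockdown array C that call was lost (adjusted p = 0.102).

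Genes of RNA polymerase I and ribosome biogenesis lay near wildtype in the knockdown cells, with a median of -0.01 that quantile normalization turned to 0.01 and leaving out wildtype array C to 0.02, 0 of 75 past either adjustment, and camera adjusted p = 0.497. Treacle partners and Treacher Collins genes had a median of -0.13 (0 of 17, camera adjusted p = 0.0714), which was -0.05 without knockdown array C, and a mean of -0.04 with 7 of 17 higher in value. The other 14 lists did not pass, with adjusted p from 0.303 to 0.996, and 0 members over all probe sets. Adjusted over the list alone, 4 rose and 1 fell of neural crest and craniofacial regulators, and 0 rose and 4 fell of the interferon response, where Tapbp was at -0.71 ± 0.12 and Ifit1 at -0.89 ± 0.17. Neurite growth and cytoskeleton and immediate early genes each had 2 that rose and 1 that fell, the heat shock response 1 and 2, endoplasmic reticulum and amino acid stress 1 and 1, apoptosis regulators 1 and 0, neuronal and catecholaminergic markers 1 and 0, and fibroblast and matrix markers 0 and 1. Cytosolic ribosomal proteins, p53 targets, sterol and fatty acid synthesis, Schwann cell and glia markers and blood and immune cell markers had 0. Camera's direction was downward against a mean or median above 0 for p53 targets, apoptosis regulators, neural crest regulators, neuronal markers, the interferon response and sterol synthesis.

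The groups did not overlap for 15.6% of probe sets, where chance gives 10%. The count of 3 was 46 among probe sets above the 40th percentile of brightness, 24 with array quality weights, 1 without the mean-variance trend and 1 with quantile normalization, and it was 103 without wildtype array C, 1 without overexpressed array A and 0 without any of the other 7 arrays.

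**Figure D3:**
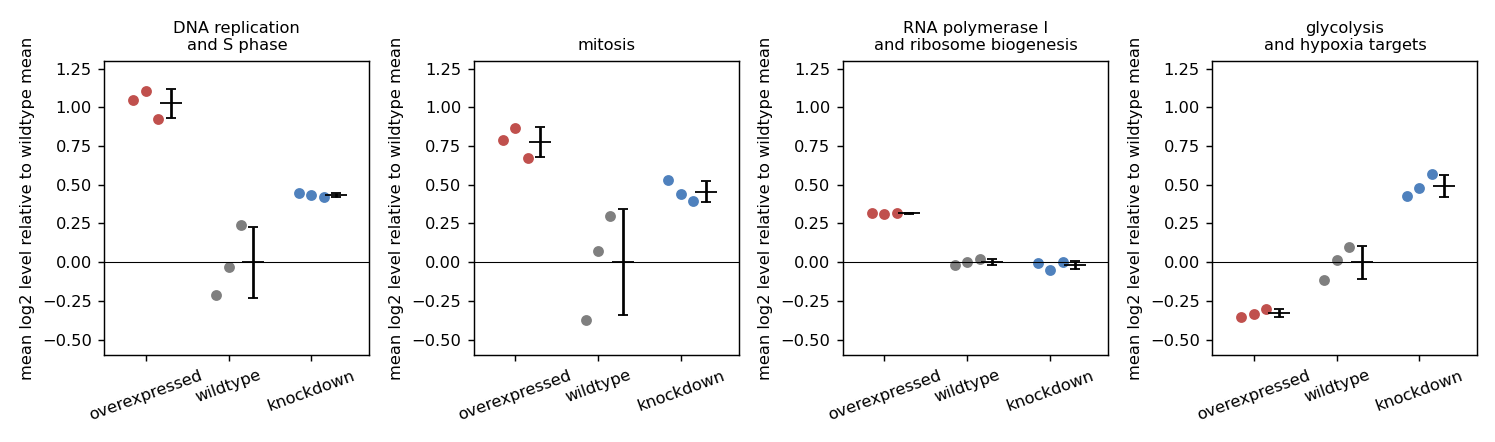
Mean log2 level of 4 gene lists on each array, relative to the wildtype mean (points, left to right A, B and C), with the group mean and SD (bars). For DNA replication the overexpressing arrays lay between 0.93 and 1.11 and the knockdown arrays between 0.42 and 0.45, and for glycolysis and hypoxia targets between -0.35 and -0.30 and between 0.43 and 0.57.

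Set directly against the knockdown cells, 23 of 75 genes of ribosome production rose and 23 of 37 glycolysis and hypoxia targets fell in the overexpressing cells. The bHLH inhibitor Id2 was higher by 2.60 ± 0.35 (adjusted p = 0.00248), Foxm1 by 2.31 ± 0.29 (adjusted p = 0.0017) on that 1 probe set, and the signalling protein gene Wnt5a by 2.04 ± 0.38 (adjusted p = 0.0111). Selenbp1 was lower at -4.28 ± 0.59 (adjusted p = 0.00258), Adm at -4.11 ± 0.36 (adjusted p = 0.000224) and the hypoxia-induced mitophagy gene Bnip3 at -3.06 ± 0.25 (adjusted p = 0.000178). In overexpressing arrays Selenbp1 read 12.3 and Adm 7.0, below the 16 added before the log, so the size of their change depends on that offset. With 1 or 64 added both calls were kept. In all, 1713 probe sets passed, 776 higher and 937 lower, for 1332 genes. The share that was higher was 45.3% here and 57.5% with a common array median.

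Of 37 glycolysis and hypoxia targets, 23 fell and 0 rose, or 27 and 1 adjusted over the list alone, with a median of -0.74 (camera adjusted p = 5.29e-17). They included Aldoc at -2.63 ± 0.15, with another probe set of opposite sign, Egln3 at -1.62 ± 0.10 and P4ha2 at -1.17 ± 0.08. Of 75 genes of RNA polymerase I and ribosome biogenesis, 23 rose and 0 fell, or 43 and 2 adjusted over the list alone, with a median of 0.35 (camera adjusted p = 1.35e-18), among them Nop56 at 1.15 ± 0.11, Tsr1 at 0.87 ± 0.11 and Polr1b, a polymerase I subunit gene, at 0.85 ± 0.12. Treacle partners and Treacher Collins genes had 5 of 17 that rose, or 10 adjusted over the list alone, and a median of 0.40 (camera adjusted p = 2.61e-10), with Nolc1 at 0.87 ± 0.12. Of 49 replication genes, 18 rose, or 34 adjusted over the list alone, with a median of 0.58, Mcm10 at 1.25 ± 0.14 and Cdt1 at 0.85 ± 0.13. Camera gave adjusted p = 2.64e-20, and adjusted p = 0.0767 with an estimated correlation. Of 47 mitosis genes, 2 rose, Nusap1 at 0.59 ± 0.15 with another probe set of opposite sign and Tpx2 at 0.50 ± 0.13, and 0 adjusted over the list alone, with a median of 0.35. The list passed camera at adjusted p = 5.33e-08, but had adjusted p = 0.415 with an estimated correlation. Fry gave adjusted p = 0.135 for the mitosis list.

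Of 43 interferon response genes, 8 fell, or 15 with 1 that rose adjusted over the list alone, with a median of -0.37 and Isg20 at -1.41 ± 0.13. By camera, adjusted p was 1.81e-05, and adjusted p = 0.207 with an estimated correlation. Of 33 sterol and fatty acid synthesis genes, 8 fell, or 12 adjusted over the list alone, with a median of -0.29 and Pmvk at -1.19 ± 0.15. In camera the list had adjusted p = 0.000874, and adjusted p = 0.457 with an estimated correlation. Of 40 fibroblast and matrix markers, 7 fell and 1 rose by either adjustment, with a median of -0.30 and fibronectin, Fn1, at -0.73 ± 0.14, with another probe set of opposite sign. Camera gave adjusted p = 0.00875, and adjusted p = 0.34 with an estimated correlation. The fibroblast median was -0.48 without knockdown array C and -0.21 without knockdown array B, and knockdown array C lay at -0.07 against 0.19 and 0.26 on A and B. Of 59 neuronal and catecholaminergic markers, 11 fell and 2 rose, or 14 and 2 adjusted over the list alone, with a median of -0.20 and Eno2 at -2.25 ± 0.15. The list passed camera at adjusted p = 0.0234, but had adjusted p = 0.34 with an estimated correlation. That call was also lost with a common array median (adjusted p = 0.0702), without the trend (0.0679), without overexpressed array B (0.109) and without knockdown array C (0.0611), and the median was -0.11 without knockdown array B.

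The other 11 lists did not pass in this comparison, with adjusted p from 0.0864 to 0.946. Members that rose and fell numbered 7 and 3 for neural crest and craniofacial regulators (7 and 5 adjusted over the list alone), with Tbx2 at 1.67 ± 0.14, 3 and 6 for endoplasmic reticulum and amino acid stress (5 and 8), with Sel1l at -0.61 ± 0.11, 1 and 7 for neurite growth and cytoskeleton (2 and 7), with Anxa2 at -1.13 ± 0.12, 1 and 4 for immediate early genes (2 and 4), with Klf10 at -0.59 ± 0.10, and 0 and 4 for oxidative phosphorylation (0 and 4), with Ndufv3 at -0.76 ± 0.09. They were 2 and 2 for the heat shock response (2 and 2), 1 and 2 for Schwann cell and glia markers (1 and 2), 0 and 2 for apoptosis regulators (0 and 2), 0 and 2 for blood and immune cell markers (0 and 2), 1 and 0 for cytosolic ribosomal proteins (1 and 0), with Rpl14 at 0.67 ± 0.13, and 0 and 0 for p53 targets (0 and 0). Camera's direction was upward against a mean below 0 for p53 targets, apoptosis regulators and neurite growth, and neural crest regulators had a mean of 0.06 and a median of -0.04 that turned to 0.06 without overexpressed array B.

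Other large differences were Srrm1 at 2.23 ± 0.25, with 1 probe set of opposite sign, Knop1 at 2.15 ± 0.37, Nolc1 by its most changed probe set at 1.88 ± 0.29, Fst at 1.77 ± 0.15, Mad1l1 at 1.72 ± 0.46, Rrp9 at 1.68 ± 0.33, Snhg1 at 1.66 ± 0.33 and Ppargc1b at 1.60 ± 0.25. No other probe set of Srrm1, Knop1, Wnt5a or Snhg1 passed. Lower were Ndrg1 at -3.54 ± 0.33, Dlk1 at -3.48 ± 0.16, Adam23 at -2.43 ± 0.22, Clu at -2.33 ± 0.28, Ace at -2.28 ± 0.27, Bhlhe40 at -2.27 ± 0.16 and Txnip at -2.23 ± 0.41. The groups did not overlap for 28.1% of probe sets, where chance gives 10%. The count of 1713 was 834 without the mean-variance trend and 1114 with a further 1.5-fold limit, and it was 704, 957 and 1127 without overexpressed array A, B or C, and 953, 908 and 1004 without knockdown array A, B or C.

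With an estimated correlation, the camera calls that held were DNA replication (adjusted p = 0.0331), RNA polymerase I and ribosome biogenesis (0.0081) and treacle partners (0.0331) in overexpressed over wildtype. In overexpressed over knockdown they were RNA polymerase I and ribosome biogenesis (0.00321), treacle partners (0.00863) and glycolysis and hypoxia targets (0.024), and in knockdown over wildtype none of the 4 calls held. By fry, 8, 3 and 11 lists passed in overexpressed over wildtype, knockdown over wildtype and overexpressed over knockdown. Among calls lost in overexpressed over knockdown, only mitosis did not pass by fry (adjusted p = 0.135). For RNA polymerase I and ribosome biogenesis the estimated correlation was 0.014, near the preset 0.01. Its adjusted p still moved from 1.23e-13 to 0.0081 in overexpressed over wildtype, so a lost call alone does not show correlated genes. The estimate was well above the preset for mitosis (0.493), sterol and fatty acid synthesis (0.303) and DNA replication (0.231). For these lists camera at the preset assumed less correlation than was estimated, so its very small p-values are overstated there.

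In limma, 0 probe sets passed in opposite directions from wildtype in overexpressing and knockdown cells, and 2 passed in the same direction. At an unadjusted p under 0.05 in both comparisons there were 107 and 982. The means were 5.48 and 292 in unchanged groups simulated against a shared wildtype group, also simulated. In the data 5209 and 2462 probe sets lay under 0.05 in overexpressed and knockdown over wildtype, and changes in either raise both counts. The simulated means therefore cannot show whether the comparisons agree or oppose. The bright probe set with no single gene symbol read 12466 ± 213.3 in overexpressing, 4811 ± 725.9 in wildtype and 8798 ± 396.1 in knockdown arrays. Arih2 was lower in both, at -0.55 ± 0.12 (adjusted p = 0.0141) and -1.0 ± 0.12 (adjusted p = 0.0336). Independent lists of these sizes would share 0.141 probe sets in opposite and 0.147 in the same direction. Unchanged groups simulated against a shared wildtype group, also simulated, shared 0 and 0. Those simulations averaged 0.02 calls in overexpressed over wildtype, so they could hardly share any, and their 0 is no measure of the overlap among real calls. Part of the excess of the 2 over 0.147 may come from the shared wildtype arrays, which that value leaves out. The covariance of the log2 fold changes was 0.0580, against 0.0403 in the simulation, with a correlation across probe sets of 0.410 against 0.499, and probe sets are not independent replicates. The count of 2 in the same direction was 24 among brighter probe sets and 9 with array quality weights, and the count of 0 in opposite directions was 5 and 3. Without wildtype array C, 1 of the shared arrays, these counts were 75 and 2. The count in the same direction was 1 without overexpressed array A and 0 without any of the other 7 arrays.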

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

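In this part, the use of the planned estimated correlation and fry as tests of the hypoxia list was chosen only after the result was seen. The single-array test of that list, set before it, was then limited to the difference between overexpressed and knockdown arrays. Outlying samples were not looked for, since each group has 3 arrays.

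Glycolysis and hypoxia targets lay below the wildtype mean on all 3 overexpressing arrays and above it on all 3 knockdown arrays, with a median difference of -0.74 between those groups that passed camera. A single array was tested as the source by leaving out each in turn. The median nearest 0 was then -0.70, which argues against it. With an estimated correlation the difference between those groups still passed (adjusted p = 0.024), which argues against correlated genes as its whole source. Neither side did so against wildtype (adjusted p = 0.195 overexpressed, 0.0905 knockdown), while by fry both did (adjusted p = 0.00407 and 0.00452). The alternatives disagree, so the position of wildtype between those groups stays open. A change with Tcof1 level, or differences in cell density or oxygen at harvest, which the labels do not record, may each be behind it and stay open.

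Genes of RNA polymerase I and ribosome biogenesis also lay on opposite sides of the wildtype mean, above on all 3 overexpressing and below on all 3 knockdown arrays, with a median difference of 0.35 that passed camera. The knockdown arrays lay between -0.05 and -0.00085 on the log2 scale, within the wildtype spread of 0.02 (SD) for all but the lowest.

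Among 64 control probe sets, 0 differed from wildtype in limma in either comparison, with 4 and 0 at an unadjusted p under 0.05. The 3' to 5' signal ratio of actin was 1.0 ± 0.018 in overexpressing, 0.958 ± 0.060 in wildtype and 0.950 ± 0.039 in knockdown arrays. The 3' probe set of 18S ribosomal RNA read 4437 on overexpressed array A against 11672 and 12849 on B and C, and 4324 on knockdown array C against 13953 and 15933 on A and B. Without overexpressed array A, 1197 probe sets passed in overexpressed over wildtype and 704 in overexpressed over knockdown, and without knockdown array C, 1976 and 1004. Counts also fell without arrays of higher 18S signal. Without overexpressed array B or C they were 1288 and 1534 in overexpressed over wildtype, and 957 and 1127 in overexpressed over knockdown. The latter was 953 and 908 without knockdown array A or B.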

How the results depend on the processing

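The chromosome adjustment was the alternative chosen after seeing the data. The cause of the changes below was not tested, except that leaving out an array, fewer probe sets and the fold limit change what is tested. Signal over background could not be judged, since the table has no detection calls.

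Probe sets changed in knockdown over wildtype numbered 46 and 24 above the 40th percentile and with array weights, 1 with quantile normalization, 1 without the trend and 1 with 6 arrays. Overexpressed over wildtype gave 1339 and overexpressed over knockdown 834 without the trend, and the latter 1114 with the 1.5-fold limit. Opposite calls numbered 5 above the percentile and 3 with weights. Same-direction calls numbered 24 above the percentile, 9 with weights, 0 with quantile normalization, 0 without the trend, and 1 each with a common median, the 1.5-fold limit and without types s, x, f, g, i and r. With an estimated correlation 3, 0 and 3 lists passed, and by fry 8, 3 and 11. On its brightest probe set, Tcof1 in knockdown over wildtype was -0.0012 with weights. The other 2 Tcof1 probe sets, at -0.22 and -0.40 in the reported fit, are not given here.

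Leaving out each array gave 1090 to 2404 probe sets in overexpressed over wildtype, 0 to 103 in knockdown over wildtype and 704 to 2048 in overexpressed over knockdown. Opposite calls ranged from 0 to 2 and same-direction calls from 0 to 75, each highest without wildtype array C. The brightest Tcof1 probe set in knockdown over wildtype ran from -0.088 to 0.130. The highest of the 3 counts came without wildtype array C, C and A. In knockdown over wildtype, sterol and fatty acid synthesis reversed to -0.090 without wildtype array A (adjusted p = 0.0382), with values up to 0.068 without wildtype array B.

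Residuals of same-letter arrays correlated between -0.012 and 0.102, over 0.1 in 1 of 9 pairs. Those of arrays with other letters in different groups correlated between -0.120 and 0.099. Such weak correlations cannot show whether the letters pair the arrays. With the letter as a block, counts were 2128, 0 and 1600, same-direction calls 0, and the fibroblast list was lost in overexpressed over wildtype (adjusted p = 0.0526).

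With chromosome medians removed, 2026, 3 and 1454 probe sets passed, 1819, 3 and 1296 of them shared with the reported calls. The gene lists, Tcof1 and the named probe sets were not retested with this adjustment. Cases were pooled over the alternatives that retested named probe sets, with each named probe set under each such alternative as 1 case. Calls in overexpressed over wildtype were kept in 1661 cases and lost in 70. Overexpressed over knockdown gave 1453 and 127, and knockdown over wildtype 23 and 33. The named probe sets were picked for large folds or small p-values, which favours keeping their calls. Of all 2169 calls in overexpressed over wildtype, 1055 were shared without wildtype array B and 2152 with array quality weights.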

Other observations

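In this part, the tests of local gene clusters, of copy number, and of shared wildtype arrays were chosen only after the results were seen, as was the chromosome analysis itself.

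Genes that share a chromosome shifted together between overexpressing and wildtype cells. Over 6096 genes with a mean above 8 on the log2 scale, on 20 chromosomes, 11 chromosome medians differed from that of all genes (permutation test, adjusted over 20), 4 higher and 7 lower. The chromosome that carries Acss2 had a median of 0.17 over 526 genes, and the one that carries Actn1 a median of -0.17 over 206 genes (each adjusted p = 0.000286, from the smallest p that 10000 permutations can give). In overexpressed over knockdown 11 chromosomes differed too, and in knockdown over wildtype 0.

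The SD of the chromosome medians was 0.0908 in overexpressed over wildtype, above the highest of 9 contrasts within groups (0.0247), which argues against array noise. Over all 12367 genes it was smaller, 0.0529, against at most 0.0218 within groups. Local clusters of co-regulated genes would leave the medians of the first and second part of each chromosome unrelated, but these correlated across chromosomes (Pearson r = 0.752, permutation p = 0.0004; Spearman rho = 0.776, permutation p = 0.001; r = 0.720 without the 2 farthest). On the chromosome most shifted in its first part, which carries Acss2, 64.6% of 263 genes in the other part lay on the same side. The exact 95% interval, 58.5% to 70.4%, treats genes as independent. Over that whole chromosome 68.6% of genes lay above the overall median, so this share was nearly known beforehand. Copy number of whole chromosomes in the overexpressing cells would give such a share and stays a candidate explanation, but any chromosome-wide cause would give it too. GC content was not tested and stays open, as does an effect of Tcof1 itself. With chromosome medians removed, 2026 probe sets passed in overexpressed over wildtype, 1819 of them among the 2169 reported. Whether the gene list results hold with chromosome medians removed was not tested.

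DNA replication genes lay above wildtype in both the overexpressing and the knockdown cells. Without 1 wildtype array, the lowest median in knockdown over wildtype was 0.30, against 0.39 with all arrays, which argues against a single wildtype array as the source. With an estimated correlation, knockdown over wildtype did not pass (adjusted p = 0.216), though by fry it did (adjusted p = 0.0415). Chance shifts of the 3 shared wildtype arrays could account for part of it and cannot be told apart from a response. Wildtype arrays spread from -0.21 to 0.24 on this list, and knockdown arrays from 0.42 to 0.45.

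Each pair of groups allows 10 splits of its 6 arrays, too few for a share under 0.05. In fits of those 6 arrays the real split gave 1757 probe sets in overexpressed over wildtype, 1 in knockdown over wildtype and 1784 in overexpressed over knockdown. The highest of the other splits gave 1, 0 and 0, so in each comparison 1 of 10 splits, the real one, gave as many.

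The 4 probe sets of Srrm1 disagreed in the knockdown, as was noticed after the values were seen. The most changed read 30.0 in knockdown and 223.5 in wildtype arrays, and the other 3 differed by -0.45 ± 0.22, 0.32 ± 0.27 and -0.41 ± 0.11, none past the threshold.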
